A study of Arabidopsis thaliana with 12 samples.

How the data were processed

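RNA from whole Arabidopsis thaliana seedlings was sequenced. The plants were 2 to 3 weeks old and grown in long days, per the labels. Total RNA was depleted of ribosomal RNA before the libraries were made. The 12 samples fall into 4 genotypes with 3 biological replicates each, per the labels: the wild type Col-0, nrpe1, a swi3b heterozygote (swi3b +/-) and idn2-1. NRPE1 is the largest subunit of RNA polymerase V, IDN2 is an RNA-binding protein of RNA-directed DNA methylation, and SWI3B is a subunit of SWI/SNF chromatin remodelling complexes.

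The values used here are 3 tables of the authors' own comparisons, 1 for each mutant against Col-0. Per the file headers, each deposited table gives an identifier, a locus, an RPKM value (reads scaled by transcript length and library size) for Col-0 and for the mutant, the log2 fold change between them, a p-value and a q-value. The submitters' processing notes name TopHat, Cufflinks and the TAIR10 genome, without tool versions. How the deposited p-values and q-values were computed is not given in the sources used here. The listed log2 values equal the log2 ratio of the deposited RPKM values to within 1.24e-05. Each table lists features with q below 0.05, the largest q being 0.0499 in the nrpe1 table, 0.0497 in the swi3b table and 0.0499 in the idn2 table. A q of 0 is given as the deposited tables print it.

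The tables hold 1 pooled value per genotype, so no spread between replicates could be computed and no gene was tested anew. A change in a gene rests on the authors' q-value. Read totals are not part of these tables, so the depth is unknown and no counting intervals are given. No column of per-sample values was left unmapped (0 columns). Whether the library protocol kept strand information is not given in the sources used here, so antisense genes and elements inside genes may share reads with the gene they overlap. The number of tests behind each table was recovered from the relation of p, rank and q under the Benjamini-Hochberg procedure. It came to 27012 for nrpe1, 25877 for swi3b and 27755 for idn2.

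Col-0 values were identical in the nrpe1 and swi3b tables for all 164 shared features with a Col-0 value above 0. In the idn2 table the Col-0 values of features shared with the nrpe1 table were 0.856 times as large (median of 134 features, 5th to 95th percentile 0.831 to 1.03). The ratios ranged from 0.476 to 1.31 and no value was identical. The Col-0 values of that table thus differ by more than one scaling factor. How they were computed is not given in the sources used here. Folds and calls were taken within a table, and levels from the idn2 table are not on the same scale as those of the others.

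Coordinates are those of the tables on TAIR10, written 1-based after adding 1 to each start. They give the whole locus, which can span several overlapping features. Gene names, classes and lengths came from the RefSeq annotation of TAIR10.1 with 37899 nuclear loci, of which 27444 are protein-coding. All 470, 616 and 752 genes of the nrpe1, swi3b and idn2 tables that matched it by identifier overlapped their reference gene, and 1, 1 and 2 genes did not match. Gene length is the annotated span with introns. Transposable elements have no entries in that annotation and were counted apart, without an enrichment test.

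The result for each mutant is the number of genes listed, per direction. Overlaps of lists were compared with n1 x n2 / N for independent lists, N being the 37899 loci, and with 100 simulations of 2 unchanged groups that share the Col-0 libraries (correlation 0.5 between comparisons, at each table's largest listed p). Fisher's exact test (two-sided) was used for overlaps, gene classes (54 tests), the gene lists (39 tests) and position near centromeres, with Benjamini-Hochberg adjustment within classes, lists and position. These tests treat genes as independent. Their background includes loci that the authors may not have tested, which lowers the p-values. For members of a list that are not in a table no p-value was used here, so no count adjusted over the list alone is given.

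The 13 gene lists (191 members used, 2 left out because their name and identifier did not agree in the annotation), the rule for named genes and most alternatives were fixed before the data were examined. Per mutant, the rule names NRPE1, SWI3B and IDN2, then the 8 largest rises and 8 largest falls among listed genes with both values above 0 and the higher at least 5 RPKM. It then takes listed members of the lists, at most 6 per list by size, and at most 10 genes listed in all 3 tables in the same direction by their smallest change. Any other gene named was chosen after its values were seen. A further 4 lists were written after the leading genes of each table had been seen. The members of the lists for touch and wounding and for starvation had not yet been seen, and those for morning and evening included clock genes already seen. Pericentromeric genes are the 20% of each chromosome's genes nearest to 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5.

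Alternatives were a q below 0.01, at least 2-fold, a higher value of at least 1 or 5 RPKM, protein-coding genes alone, a Bonferroni adjustment, other backgrounds and a pseudocount of 1 RPKM. The tests of elements in gene loci and of neighbouring genes were written for all annotated genes; counting protein-coding genes alone is a narrower form added later. Correlations among the shared calls of the simulations, pooled, were also added later. Bootstrap intervals (95%) used 10000 resamples and the test of neighbouring genes 1000 random draws. The functions were tested on simulated data with 200 shared changes planted among 25877 features for nrpe1 and swi3b, and all 200 were found. The planted changes were far larger than the calling limit. Their recovery therefore checks the functions and does not measure how many real shared changes would be found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.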

Results

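The series title links a SWI/SNF nucleosome remodelling complex with silencing by non-coding RNA, and the design sets 3 mutants against the wild type Col-0. RNA-seq of rRNA-depleted total RNA covered 12 seedling samples, 3 for each of Col-0, nrpe1, swi3b +/- and idn2-1. The idn2-1 samples are numbered apart from those of the other genotypes. Whether all libraries were made together is not known here. The tables hold 1 value per genotype, so no value below has a spread between replicates, and the depth is unknown.

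In nrpe1, which lacks normal function of the largest RNA polymerase V subunit, the NRPE1 transcript (AT2G40030, chromosome 2, 16714494 to 16723583) fell from 3.98 to 1.01 RPKM in the authors' deposited table, to 25.3% of Col-0 (q = 0). Neither SWI3B in the swi3b +/- table nor IDN2 in the idn2-1 table is among the genes listed, so these 2 labels could not be checked by the level of the mutated gene.

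The comparison of nrpe1 with Col-0 asks which transcripts depend on RNA polymerase V. Several pseudogenes that were near silent in Col-0 rose strongly, and the DNA demethylase gene ROS1 fell. The authors' deposited table lists AT5G27845 (chromosome 5, 9868191 to 9872479) at 0.612 RPKM in Col-0 and 22.0 in nrpe1, a 35.9-fold rise (q = 0). At the same locus, the element AT5TE35950 rose from 1.36 to 104.8 RPKM in the authors' deposited table; reads of the gene and the element cannot be told apart. Next to one another on chromosome 5, AT5G35205 (13466904 to 13471592) rose 12.9-fold and AT5G35207 (13471681 to 13472500) 53.4-fold in the authors' deposited table (q = 0 and 0.00876). ROS1 (AT2G36490, chromosome 2, 15308021 to 15314807) fell 9.45-fold, from 8.88 to 0.939 RPKM, in the authors' deposited table (q = 0).

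Other large rises in nrpe1 were those of AT1G33840, which encodes a LURP-one-like protein, and AT2G33175, with log2 folds of 5.41 and 4.18 in the authors' deposited table (q = 0 and 0.00711). The pseudogene AT4G04293 rose 6.87-fold, and XTH18, a cell wall xyloglucan endotransglucosylase, 4.16-fold in the authors' deposited table (q = 0 for both). The transcribed pseudogene RSU1 (AT3G48130) had the largest rise among genes of at least 5 RPKM in either genotype and above 0 in both, from 4.05 to 246.8 RPKM in the authors' deposited table (q = 0.00563). Its locus is shorter than those of the other largest rises and falls named in nrpe1. Among the falls, the non-coding genes AT2G06002 and AT1G58590 fell 16.8-fold and 4.16-fold in the authors' deposited table (q = 2.04e-05 and 5.54e-12). The microRNA precursor MIR863 fell 4.09-fold and COR27, a cold- and clock-regulated gene, 3.20-fold in the authors' deposited table (q = 0.000746 and 0). The locus given for MIR863 spans 3933 bp, and which transcript its reads came from was not tested. AT1G45163, AT1G12730 and AT1G56090 fell 4.41-fold, 3.00-fold and 3.00-fold in the authors' deposited table.

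Altogether, the authors' deposited table for nrpe1 lists 471 genes, 270 higher and 201 lower than Col-0. It also lists 38 transposable elements, 10 higher and 28 lower. All 38 lie in loci that overlap an annotated gene. When protein-coding genes alone are counted, 26 of the lower elements lie in loci that overlap one, against 6 of the 10 higher ones (Fisher's exact test, two-sided, p = 0.0314). The positions of the elements within these loci were not used. Pseudogenes made up 8 of the higher genes and 2 of the lower ones. As a class they were less often listed than other annotated loci (odds ratio 0.264, 95% interval 0.113 to 0.529, adjusted p = 2.56e-05 for higher; Fisher's exact test), in a background that includes pseudogenes with no transcript.

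**Figure D1:**
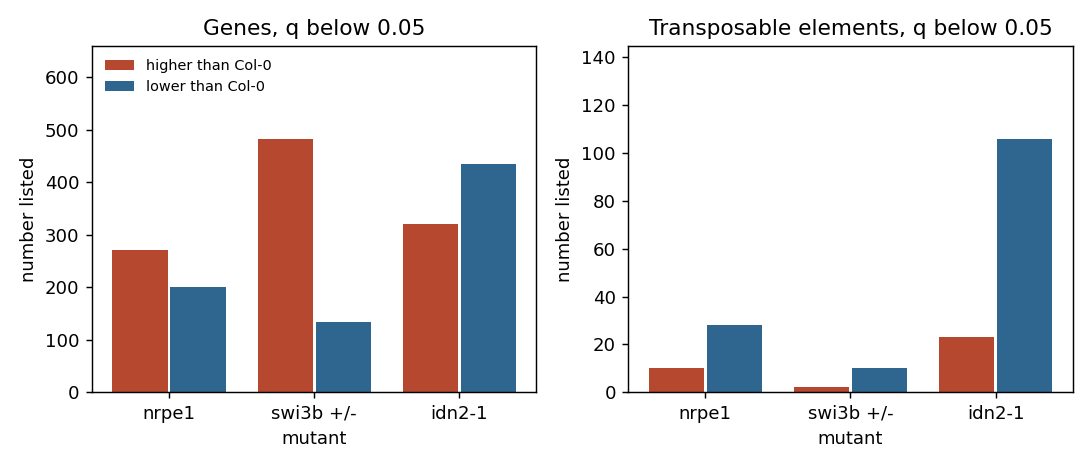
Number of genes (left) and transposable elements (right) listed with q below 0.05 in the authors' deposited table of each mutant, higher (red) or lower (blue) than Col-0. Higher genes outnumber lower ones in nrpe1 (270 and 201) and swi3b +/- (483 and 134), and lower genes outnumber higher ones in idn2-1 (434 and 320).

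Among the fixed lists in nrpe1, 4 of 18 circadian clock genes were listed (odds ratio 22.9, 95% interval 5.48 to 73.4, adjusted p = 0.000809, Fisher's exact test). CCA1, LNK1 and LNK2, which act in the morning, rose 2.11-fold, 1.95-fold and 1.60-fold, and PRR3 fell 1.73-fold, in the authors' deposited table. At a minimum of 2-fold 1 of these members was left and the enrichment was lost (adjusted p = 0.484, Fisher's exact test). The silencing machinery list had 2 of 28 members listed, NRPE1 and ROS1, both lower (adjusted p = 0.183, Fisher's exact test). SDC, a target of silencing by DNA methylation, rose 3.09-fold from 0.692 RPKM in the authors' deposited table (q = 0.0187), as 1 of 3 members of its list (adjusted p = 0.159). SWI3D, a SWI/SNF subunit gene, rose 1.55-fold in the authors' deposited table (q = 0.0444; list adjusted p = 0.417). The defence genes NIMIN1 and WRKY70 rose 2.38-fold and 1.67-fold in the authors' deposited table (list adjusted p = 0.147). In the jasmonate list JAZ5 rose 1.89-fold and VSP2 fell 1.63-fold in the authors' deposited table (list adjusted p = 0.147). COR15B of the cold list had a log2 fold of -0.58 in the authors' deposited table (list adjusted p = 0.535).

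The comparison of swi3b +/- with Col-0 asks which transcripts respond to a reduced dose of the SWI/SNF subunit. Listed genes of the jasmonate and defence lists rose, as did PHI-1 and ACS6, and MRD1, ERD5 and MIOX2 fell. The authors' deposited table lists 617 genes, 483 higher and 134 lower. It also lists 12 transposable elements, 2 higher and 10 lower. All 12 lie in loci that overlap an annotated gene, and 5 of the lower and 2 of the higher ones lie in loci that overlap a protein-coding gene (Fisher's exact test, p = 0.470).

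Among genes of at least 5 RPKM in either genotype and above 0 in both, the largest rises in swi3b +/- were AT1G33760, an AP2/ERF-type transcription factor gene, and AT3G09870, a SAUR-like gene, with log2 folds of 4.14 and 3.67 in the authors' deposited table (q = 3.02e-10 and 0.00209). PHI-1 rose 8.04-fold, from 11.6 to 93.0 RPKM, and ACS6, an enzyme of ethylene synthesis, 7.13-fold in the authors' deposited table (q = 0 for both). AT4G29780, the zinc finger gene SZF1, the abscisic acid hydroxylase gene CYP707A3 and AT5G19240 rose 6.74-fold, 6.36-fold, 6.18-fold and 5.89-fold in the authors' deposited table. MRD1 (AT1G53480, chromosome 1, 19963047 to 19969757) had the largest fall within the same limits, 9.05-fold from 37.7 to 4.17 RPKM in the authors' deposited table (q = 0). ERD5, which encodes proline dehydrogenase, fell 4.34-fold and MIOX2, a myo-inositol oxygenase, 3.75-fold in the authors' deposited table. SIP2 and SEN1, a gene induced by darkness, fell 3.02-fold and 2.99-fold in the authors' deposited table (q = 6.87e-09 and 9.22e-10). PYL6, GDPD2 and the locus of MIR863 fell 3.34-fold, 3.26-fold and 2.73-fold in the authors' deposited table.

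Of the 19 jasmonate and wounding genes, 9 were listed in swi3b +/-, all of them higher (odds ratio 55.2, 95% interval 19.8 to 152, adjusted p = 2.33e-10, Fisher's exact test). TAT3, JAZ5 and VSP1 rose 4.02-fold, 3.01-fold and 2.61-fold in the authors' deposited table. JAZ1, MYC2 and VSP2 rose 2.24-fold, 1.91-fold and 1.88-fold in the authors' deposited table. Of 22 salicylic acid and defence genes, 4 were listed and all 4 were higher (odds ratio 13.5, 95% interval 3.32 to 41.2, adjusted p = 0.00391, Fisher's exact test). WRKY70, WRKY33, CBP60G and WRKY53 rose 2.99-fold, 2.62-fold, 2.25-fold and 2.15-fold in the authors' deposited table. A list for touch and wounding, written later, had 21 of 24 members listed in swi3b +/-, all higher. Whether the jasmonate and defence genes rose through the mutation or through handling of the plants was not tested. The clock list had 5 of 18 members listed (odds ratio 23.5, 95% interval 6.53 to 70.4, adjusted p = 0.000157, Fisher's exact test). CCA1, LNK1 and LNK2 rose 3.02-fold, 2.40-fold and 1.74-fold, and PRR5 and FKF1, which act later in the day, fell 2.12-fold and 2.07-fold in the authors' deposited table. CBF2 and P5CS1 of the cold and drought list rose 2.19-fold and 1.82-fold in the authors' deposited table (list adjusted p = 0.147). GOLS1 rose 2.08-fold and the flowering repressor MAF5 fell 2.36-fold in the authors' deposited table (Fisher's exact test of their lists, p before adjustment 0.231 and 0.192). No member of the silencing machinery, known silenced target or SWI/SNF lists was listed in swi3b +/-.

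**Figure D2:**
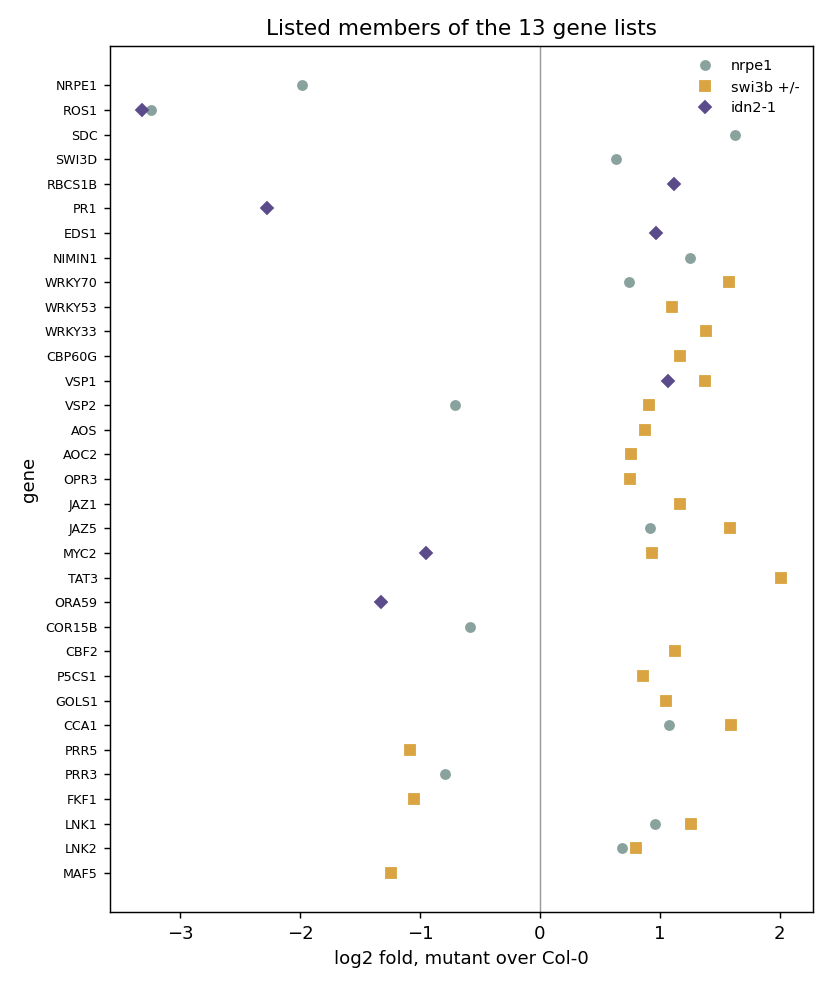
Log2 fold change over Col-0 of each member of the 13 fixed gene lists that is listed in the authors' deposited table of nrpe1 (circles), swi3b +/- (squares) or idn2-1 (diamonds). Every listed jasmonate gene of swi3b +/- lies right of 0, and ROS1 lies near -3.24 in nrpe1 and -3.32 in idn2-1.

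The comparison of idn2-1 with Col-0 asks which transcripts depend on the RNA-binding protein IDN2. ROS1, MRD1 and the trehalose phosphatase gene TPPI fell strongly, 23 of 287 annotated snoRNA genes were listed as higher, and most listed transposable elements fell. The direction of change also followed gene length in this table. Of listed protein-coding genes in the shortest of 3 equal length classes (up to 1597 bp), 149 of 209 were higher (71.3%), against 40 of 256 in the longest class, above 2644 bp (15.6%; Fisher's exact test, two-sided, p = 2.96e-35). The same shares were 85.9% and 70.6% in swi3b +/- (p = 0.000409) and 50.3% and 62.6% in nrpe1 (p = 0.0593; Fisher's exact test).

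**Figure D3:**
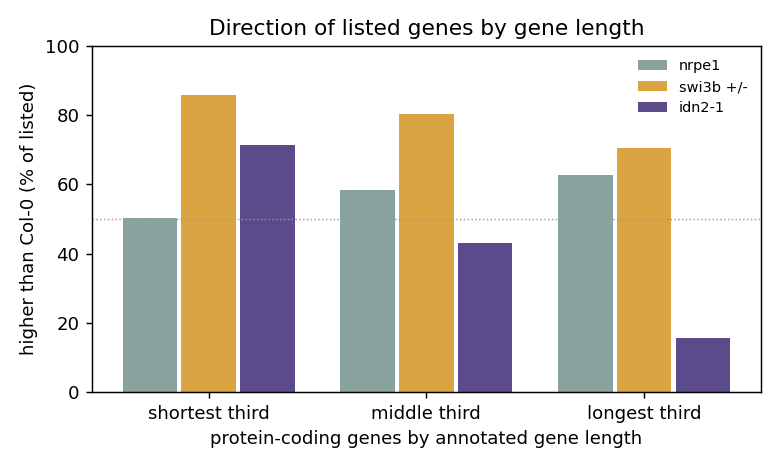
Share of listed protein-coding genes that are higher than Col-0 (percent), by class of annotated gene length (3 equal classes of protein-coding genes), for nrpe1, swi3b +/- and idn2-1; the dotted line marks 50%. In idn2-1 the share is 71.3% in the shortest class, 43.2% in the middle and 15.6% in the longest.

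The authors' deposited table for idn2-1 lists 754 genes, 320 higher and 434 lower (50 higher and 38 lower under a Bonferroni adjustment, so the balance depends on the threshold), and 129 transposable elements, 23 higher and 106 lower. TPPI (AT5G10100, chromosome 5, 3157980 to 3161708) fell 25.4-fold, from 107.5 to 4.24 RPKM, and MRD1 12.6-fold in the authors' deposited table (q = 0 for both). ROS1 fell 9.96-fold, from 8.58 to 0.862 RPKM, in the authors' deposited table (q = 0). AT2G07698, annotated as an ATPase alpha subunit, and the jumonji gene MEE27 fell 8.72-fold and 7.77-fold in the authors' deposited table (q = 0 for both). Whether reads of mitochondrial transcripts were counted at AT2G07698 was not tested. AT1G76892, the U1 snRNA gene U1.5 and AT1G45163 fell 7.59-fold, 5.68-fold and 5.59-fold in the authors' deposited table. By the same limits of level the largest rises were ARP1, an RNA-binding protein gene, at 18.6-fold and MPC at 10.7-fold in the authors' deposited table (q = 1.17e-12 and 0.00237). PHI-1, AT5G19240, TBL8, AT1G65490 and AT1G65486 rose 8.90-fold, 6.64-fold, 6.25-fold, 5.83-fold and 5.61-fold in the authors' deposited table. For TBL8 the Col-0 value was 0.556 times the value that the common scaling with the nrpe1 comparison gives. The size of its rise is therefore uncertain.

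All 23 listed snoRNA genes in idn2-1 were higher, out of 287 annotated (odds ratio 10.9, 95% interval 6.71 to 17.1, adjusted p = 5.95e-15, Fisher's exact test). The largest of these rises was that of AT1G74456, 5.95-fold in the authors' deposited table (q = 0.0375). The loci of these genes are short, with a median of 85 bp, and AT2G20721 and AT3G21805 have the same values (10119.6 RPKM in idn2-1) in the authors' deposited table, so these 2 are uncertain; whether copies share reads was not tested. Among elements, 99 of the 106 lower ones lie in loci that overlap an annotated gene, against 17 of the 23 higher ones (Fisher's exact test, p = 0.0125). With protein-coding genes alone these were 93 and 14 (Fisher's exact test, p = 0.00442). Of 15 listed pseudogenes 14 were lower. In these rRNA-depleted libraries the 18S rRNA gene AT3G41768, the only one listed of 4 annotated rRNA genes, fell 5.27-fold from 19.0 to 3.61 RPKM in the authors' deposited table (q = 2.68e-12). The non-coding gene AT3G41761 beside it, named after its values were seen, fell 5.34-fold in the authors' deposited table (q = 0.00126).

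Few list members were listed in idn2-1. The smallest fold among its listed genes with both values above 0 was 1.86, against 1.47 in nrpe1 and 1.55 in swi3b +/-. A member with a smaller change is therefore not listed here and cannot be called unchanged. The jasmonate list had 3 of 19 members listed (odds ratio 9.29, 95% interval 1.73 to 32.6, adjusted p = 0.0464, Fisher's exact test), with VSP1 up 2.09-fold and ORA59 and MYC2 down 2.51-fold and 1.93-fold in the authors' deposited table. That call by Fisher's exact test was lost against protein-coding genes alone (adjusted p = 0.0845), at 2-fold (adjusted p = 0.256) and at q below 0.01, where no member was listed. PR1, a marker of salicylic acid responses, fell 4.85-fold and EDS1 rose 1.96-fold in the authors' deposited table (list adjusted p = 0.248). RBCS1B rose 2.17-fold in the authors' deposited table (list adjusted p = 0.838). No clock member was listed in idn2-1. No member of the flower organ, root or seed storage marker lists was listed in any of the 3 tables.

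Whether the mutants change the same genes is the question that joins the comparisons. The nrpe1 and swi3b +/- tables shared 157 genes in the same direction, 136 higher and 21 lower, where 4.15 would be shared by independent lists (Fisher's exact test p = 4.99e-188 for higher and 5.86e-25 for lower). Unchanged groups compared with shared Col-0 libraries gave a mean of 1.03 and at most 3 in 100 simulations. These simulations hold chance variation alone. They cannot show how many shared genes would arise if the Col-0 plants differed as a set for a reason other than genotype. The nrpe1 and idn2-1 tables shared 109 genes in the same direction, 71 higher and 38 lower (4.58 for independent lists; mean 1.41 in simulations), and swi3b +/- and idn2-1 shared 162, 121 higher and 41 lower (5.61 for independent lists; mean 1.67). All 3 comparisons use Col-0 libraries that could not be split, so part of each excess may come from the shared controls. With genes listed in any table as the background, which by its make-up leaves out genes listed nowhere, the same-direction ratios were 1.46 for nrpe1 and swi3b +/-, 0.920 for nrpe1 and idn2-1 and 1.12 for swi3b +/- and idn2-1. Such a background makes lists exclude each other by its make-up, so a ratio near or below 1 there is not read as a lack of overlap. In the same order of pairs the ratios there were 1.53, 1.204 and 1.15 for higher genes and 1.14, 0.638 and 1.03 for lower genes.

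Same-direction genes made up 96.9% of the 162 genes listed in both nrpe1 and swi3b +/-, 94.0% of the 116 in nrpe1 and idn2-1, and 98.2% of the 165 in swi3b +/- and idn2-1. In the simulations of unchanged groups that share was 100%, so a high share does not separate real from chance overlap. Across these genes, which are not replicates, the log2 folds had a Pearson correlation of 0.797, 0.753 and 0.875 and a Spearman correlation of 0.7003, 0.689 and 0.668. Listing sets higher and lower genes apart, and shared calls of the simulated unchanged groups, on the scale of their test statistic, gave a Pearson correlation of 0.992, 0.992 and 0.993, so these values do not separate real from chance overlap either. Within shared higher genes the Pearson correlation was 0.519, 0.574 and 0.483, and within shared lower genes 0.676, 0.593 and 0.499. The simulated values were -0.0827, -0.0249 and 0.371 for higher and 0.223, 0.151 and -0.0645 for lower calls. They rest on 51 to 86 pooled calls per direction and on test statistics, while the observed values are of log2 folds. Expression level was not simulated, so the gap between simulated and observed values does not decide whether the overlap is real. Covariances over all genes were not computed, since only listed genes have values here.

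**Figure D4:**
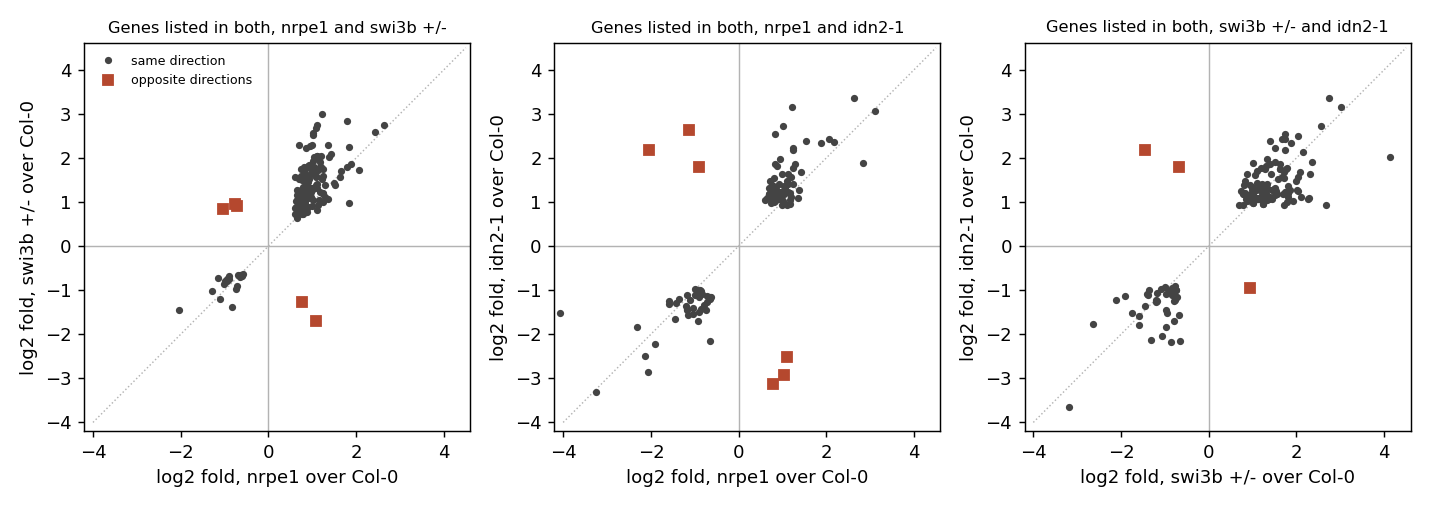
Log2 fold change over Col-0 of genes listed in both tables of each pair of mutants, from the authors' deposited tables; genes with a value of 0 are not drawn, and the dotted line marks equal change. Genes in opposite directions (squares) number 5 for nrpe1 and swi3b +/-, 7 for nrpe1 and idn2-1 (1 of them with a value of 0 and not drawn) and 3 for swi3b +/- and idn2-1.

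In all 3 tables, 63 genes changed in the same direction, 56 higher and 7 lower. The non-coding gene AT3G29644 (chromosome 3, 11497888 to 11501366) rose by a log2 fold of 2.64 in nrpe1, 2.74 in swi3b +/- and 3.35 in idn2-1 in the authors' deposited tables. XTH18, XTR6 and the touch-induced calmodulin-like gene TCH2 rose by log2 folds of 2.06, 1.53 and 1.37 in nrpe1 and 1.73, 1.39 and 2.01 in swi3b +/- in the authors' deposited tables. PHI-1 rose by 1.22, 3.01 and 3.15 in nrpe1, swi3b +/- and idn2-1 in the authors' deposited tables. AT2G35658, AT1G13650, the ubiquitin ligase gene CMPG1 and AT5G02230 followed, with smallest log2 folds of 1.87, 1.42, 1.28 and 1.23, and AT1G76600 rose from 8.93 to 21.2 RPKM in nrpe1, in the authors' deposited tables. ROS1 fell in nrpe1 and idn2-1 and was not listed in swi3b +/-; MRD1 fell in swi3b +/- and idn2-1 and was not listed in nrpe1. Whether these genes differ between the mutants was not tested.

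Listed genes of every mutant were less often pericentromeric than annotated loci (20%). The shares were 12.6% of higher and 9.45% of lower genes in nrpe1 (odds ratios 0.577 and 0.416, adjusted p = 0.00212 and 9.42e-05), 10.2% and 4.48% in swi3b +/- (0.449 and 0.187, adjusted p = 4.54e-08 and 1.10e-06), and 12.5% and 11.8% in idn2-1 (0.569 and 0.532, adjusted p = 0.000662 and 1.39e-05; Fisher's exact test). Without pseudogenes in the list and background, only the lower genes of swi3b +/- remained past the threshold (odds ratio 0.262, adjusted p = 0.00381, Fisher's exact test).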

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

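The tests of the hour of harvest, of one scaling factor in idn2-1, of the shared higher and lower genes taken apart, and of elements over protein-coding genes alone were chosen after the results had been seen. The differences given here are between genes that the authors called in opposite directions, and the differences themselves were not tested. Genes in opposite directions numbered 5 for nrpe1 and swi3b +/-, 7 for nrpe1 and idn2-1, and 3 for swi3b +/- and idn2-1.

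From the authors' deposited tables, the log2 fold of VSP2 was 1.62 higher in swi3b +/- than in nrpe1 and that of GDPD2 differed by -2.79. Between idn2-1 and nrpe1, the authors' deposited tables gave differences of -3.61 for U1.5, -3.96 for AT1G76892, -3.90 for AT2G07698, 3.78 for TBL8 and 4.22 for MIR863. The source of the reads at AT2G07698 was not tested. Between idn2-1 and swi3b +/-, the authors' deposited tables gave -1.88 for MYC2 and 3.63 for MIR863. For TBL8 and MIR863 the Col-0 value itself differed between the tables, at 0.556 and 0.639 times the value that the common scaling gives.

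The genes shared by nrpe1 and swi3b +/- may reflect the Col-0 libraries, how plants were handled, or the mutants; Col-0 alone would leave both mutants at the same level. At shared higher genes the median log2 of swi3b +/- over nrpe1 was 0.31 (95% bootstrap interval 0.24 to 0.49) and at shared lower genes 0.0377 (-0.05 to 0.16). The test written before the result was seen was met if either median lay near 0. The lower genes met it, so Col-0 alone stays open as an explanation for them. The difference of the medians was 0.28 (0.10 to 0.46), narrowly past a limit set after the results had been seen. These intervals measure the spread across genes and not between replicates, so they do not decide against Col-0 alone for the higher genes. Handling and an effect of the mutations also remain open: the list for touch and wounding, whose theme was chosen from the leading genes, was enriched among shared higher genes (7 of 24 members, odds ratio 120.2, p = 2.16e-12, Fisher's exact test). The hour of harvest could not be decided: the directions of most listed clock genes had been seen before that test (p = 0.0286 in swi3b +/- and 0.0667 in nrpe1 with them), and without them 1 morning gene was higher and 1 evening gene lower in swi3b +/- (p = 1, Fisher's exact test).

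In idn2-1 all 23 listed snoRNA genes, of 287 annotated, were higher and 106 of 129 listed elements lower, which argues against one scaling factor (17.83% of listed elements and 100% of listed snoRNA genes were higher). A shift by length between the libraries, such as from RNA quality or size selection, remains open for idn2-1 and could account for part of the table (Fisher's exact test, p = 2.96e-35 between the shortest and longest classes; 65.9% and 8.21% higher among genes in no other table, p = 2.53e-30; 80.8% and 48.9% among genes shared in direction with another table, p = 0.000523). nrpe1 genes in no other table went the other way (29.6% and 57.4%, Fisher's exact test, p = 0.00110). Lower elements lay in gene loci more often than higher ones (Fisher's exact test, p = 0.0125 for any annotated gene and 0.00442 for protein-coding genes), so reads of overlapping genes are a candidate source of their values. Uneven depletion of rRNA (AT3G41768 fell) and an effect of idn2-1 remain untested, because the genotype and its libraries cannot be separated.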

How the results depend on the processing

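No paired analysis was possible because the tables hold 1 value per genotype; leaving out replicates, other count tests and other filters on replicate values were not run for the same reason. The depth is unknown, so what it limits could not be measured. Settings added after seeing the data were elements included, Col-0 agreement between tables, protein-coding genes for overlaps, elements and neighbours, and the implied number of tests as background. Restriction to nuclear genes removed nothing (32 alternatives) and says nothing about stability; of the other 145 alternatives, 113 kept their direction and side of the threshold in both directions tested or, without a test, stayed within 1.5 times or the 95% binomial interval. Counts of listed genes fell at q below 0.01 to 259 in nrpe1 and 316 in idn2-1, at 2-fold to 191 in nrpe1 and 368 in swi3b +/-, and under Bonferroni to 112, 205 and 88 in nrpe1, swi3b +/- and idn2-1, by construction. With Bonferroni 56.8% of idn2-1 genes were higher, against 42.4%. Shared genes fell at q below 0.01 to 88 (nrpe1 and swi3b +/-), 54 (nrpe1 and idn2-1) and 86 (swi3b +/- and idn2-1), and at 2-fold to 52 and 51 for the first and second pair. At q below 0.01, 100% of genes shared by swi3b +/- and idn2-1 had the same direction, and elements with genes that are not protein-coding fell to 46, 13 and 132. With listed genes as background, where the lists themselves make up the background, overlap ratios were 1.46 (nrpe1 and swi3b +/-) and 1.12 (swi3b +/- and idn2-1), no longer past the threshold for lower genes, and 0.920 (nrpe1 and idn2-1). Clock genes in nrpe1 fell to 1 at 2-fold; jasmonate genes in idn2-1 fell to 0 at q below 0.01 and 2 at 2-fold, and their 3 members lost the call against protein-coding genes (adjusted p = 0.0845) and the implied number of tests (adjusted p = 0.109, Fisher's exact test). Without pseudogenes, pericentromeric odds ratios were 0.774 and 0.667 in nrpe1 (higher, lower), 0.758 in swi3b +/- (higher), and 0.936 and 0.728 in idn2-1 (higher, lower), no longer past the threshold; the cause was not tested.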

Other observations

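Genes of darkness and sugar starvation, a list written after the leading falls of swi3b +/- had been seen but with members not yet seen, had 8 of 13 members listed in swi3b +/-, 7 lower and 1 higher (odds ratio 98.0, adjusted p = 3.35e-11, Fisher's exact test over 12 tests). This theme came from the falls in the same comparison, so the p-value is not independent support. ASN1, an asparagine synthetase gene, fell 2.25-fold and GDH2 2.35-fold, and DIN11 rose 2.05-fold, in the authors' deposited table. The list for touch and wounding had 21 of 24 members listed in swi3b +/-, 7 in nrpe1 and 5 in idn2-1, all higher (odds ratios 438, 33.3 and 13.1; adjusted p = 4.45e-34, 4.98e-08 and 0.000189, Fisher's exact test). Its theme was chosen from the leading genes of the same tables, with members not yet seen, so these p-values are not independent support. ZAT12 rose 4.16-fold and TCH4 4.11-fold in swi3b +/- in the authors' deposited table. Of the morning list, which like the evening list held clock genes already seen, 4 of 14 members were listed in nrpe1 and 4 in swi3b +/-, all higher (adjusted p = 6.36e-05 and 0.000146), and of the evening list 2 of 11 and 3 of 11, all lower (adjusted p = 0.0118 and 0.00110, Fisher's exact test); neither list had a member in idn2-1.

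APR1 and APR2, enzymes of sulphate reduction chosen after their values were seen, rose in all 3 mutants. APR1 rose 1.99-fold, 3.31-fold and 1.90-fold in nrpe1, swi3b +/- and idn2-1 in the authors' deposited tables.

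Neighbouring genes may change together, as a hypothesis written before its test. In nrpe1, 21 same-direction pairs of listed genes started within 10 kb of each other, against a median of 9 and a 95th percentile of 15 in 1000 random draws (permutation test, p = 0.000999, the smallest these draws can give). The counts were 55 pairs in swi3b +/- (median 21) and 60 in idn2-1 (median 24), with the same p. The draws kept the number of genes per chromosome and were not matched for expression or distance from the centromere. The excess therefore does not separate neighbours that change together from where expressed genes lie. Counting protein-coding genes alone, a form added after the test was written, gave 16 pairs in nrpe1 (median 8, highest draw 19, permutation test, p = 0.0140). It gave 54 pairs in swi3b +/- (highest draw 38) and 43 in idn2-1 (highest draw 37). Tandem copies and overlapping genes that share reads or regulation were not separated from other neighbours.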
